A study of Arabidopsis thaliana with 6 samples.

How the data were processed

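Leaf RNA of Arabidopsis thaliana was measured by RNA-seq in 2 libraries, 1 from wild type (Col-0) plants and 1 from plants labelled jmj16, an insertion allele in the same background. The series holds 6 samples. The other 4, chromatin immunoprecipitation samples for the histone mark H3K4me3 and for an HA-tagged JMJ16 protein, were not analysed here. The labels describe fully expanded leaves 5 and 6 without visible yellowing, from plants kept 6 days on plates and then on soil at 22 °C with 16 h of light and 8 h of dark. The labels conflict on age: the sample characteristics give 4 weeks and the source names give 5 weeks.

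The authors deposited 1 table per library with an estimated count of reads for each transcript model, not normalized and not always whole, in the layout Salmon writes per the file headers. The same deposited tables give TPM, a relative abundance scaled by transcript length and by the library's own total. Salmon, TopHat2, Bowtie2, SAMtools and deepTools and the genome build TAIR10 are named, without roles or versions, per the submitters' processing notes. The Salmon version, the annotation release, the read layout, the strandedness and any trimming are not given in the sources used here. Salmon divides reads that fit several transcripts among them, so near-identical paralogs share reads and their values are uncertain. Without a stated strand setting, reads of overlapping genes cannot be told apart.

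The tables hold 48359 transcript models of 27655 gene loci. Estimated counts and TPM were summed over the transcripts of a locus, and the summed counts were rounded to whole numbers. Symbols came from a RefSeq gene table of assembly TAIR10.1, which matched 27445 loci. The 210 loci without a match carry organelle identifiers. Because that assembly name differs from the build in the labels, no coordinates are printed. JMJ16 was taken as locus AT1G08620 from general knowledge, since the reference lists that locus as PKDM7D.

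The wild type library holds 10643186 estimated counts and the jmj16-labelled library 13844284. Library sizes were scaled with TMM factors of 0.969 and 1.03 from edgeR 4.0.16 (R 4.3.3), which was used for scaling only. The log2 ratio of the jmj16-labelled library over wild type was taken after adding 0.5 to each count. A gene was called measured with at least 20 reads over both libraries, which left 17151 genes. A measured gene was called higher or lower when it differed by at least 2-fold and the exact (Clopper-Pearson) 95% counting interval of its ratio excluded 1. Intervals of single counts are exact Poisson intervals. All of these cover counting error only: reads are not independent molecules, and there is 1 library per genotype, so no difference has a replicate check and no p-value is given. Where a library had 0 counts, the fold is a bound against a floor of 3 counts in that library.

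The 24 gene lists, the size rule and the rule for named genes were fixed before the data were examined. Of 358 list members, 7 were left out because the reference did not carry their name: JMJ17, JMJ19, YLS3, SGRL, DVR, SARD4 and TIP41L. For each list the median log2 ratio of its measured members was set among 10000 random lists of the same size, matched on expression in 20 bins, and again matched on transcript length and expression in 10 by 10 bins. The percentile is a description of these libraries. Only the matching on expression was part of the plan. The percentile printed is the one matched on length and expression unless stated. The 95% interval of a list's median is the exact binomial one over its members, and for lists under 6 members it is the range. The genes named were JMJ16, then WRKY53 and SAG201, which the published study singles out. For each list they were up to 4 members passing the rule, largest difference first. Where fewer than 2 passed, the 2 members with most reads were named. The 10 highest and the 10 lowest log2 ratios among passing genes with a symbol and at least 100 reads completed the rule. The value of 1 gene that the rule names is not reported here. Members named beyond this rule, so that small counts can be read, were chosen after their values were seen and are introduced with the word "also".

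Alternatives were median-of-ratios, total-count and upper-quartile scaling, log2(TPM + 1), an added count of 5, the most abundant transcript of each gene alone, no minimum or a minimum of 100 reads, folds of 1.5 and 4, and a counting interval wholly beyond 2-fold. A correction of the log2 ratio for its trend with transcript length (lowess, span 0.3) was added after the trend had been seen. A planned test of scaling as the cause of the lower H3K4 enzymes was dropped after its result was seen, because the scalings differ too little for it to have come out otherwise. The planned comparison of JMJ16 with 200 genes of like length and expression was first set against the reads that remain, and is given here for its lower count, which is what it can test. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

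The steps were tested on simulated counts for the comparison of the jmj16-labelled with the wild type library. Counts were simulated with 50 genes raised and 50 lowered 3-fold, and as many 6-fold; 17097 genes reached the minimum of reads, and some of the lowered genes did not. All 50 genes raised 3-fold and all 50 raised 6-fold passed, as did 46 of 50 lowered 3-fold and 47 of 50 lowered 6-fold. Of 16902 unchanged genes, 74 passed. Of 200 random unchanged lists, simulated without a length trend and matched on expression alone, 9.5% fell outside the 5th to 95th percentile. Percentiles matched on length and expression were not tested this way. With a simulated length trend in 17126 genes, 284 of 16929 unchanged genes passed, and 67 did after the length correction. That trend was a straight line in log2 length, while the observed one fell faster among the longest transcripts. In the observed longest decile the median was -0.87 and 705 of 1715 genes were lower. The simulated counts therefore do not estimate the false calls in the real libraries.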

Results

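The question behind the 2 RNA-seq libraries was how the leaf transcriptome differs without JMJ16, a demethylase of lysine 4 of histone H3 (H3K4) that the series title links to leaf senescence. Mature rosette leaves of wild type and of plants labelled as the jmj16 insertion line were compared, with 1 library each. The libraries held 10643186 estimated counts (wild type) and 13844284 (jmj16-labelled), and the 100 most abundant genes took 35.7% and 30.6% of them. Genes of the chloroplast and mitochondrial genomes took 2.35% and 1.61%. Across genes, log2(TPM + 1) of the libraries had a Pearson r of 0.953, where genes are not independent replicates. Every difference given here is between these 2 libraries and has no replicate check.

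JMJ16 itself (AT1G08620) was still read in the library labelled jmj16. It had 188 estimated counts in wild type (95% Poisson interval 162 to 217) and 168 in the jmj16-labelled library (144 to 195), or 3.61 and 2.44 TPM. Its log2 ratio was -0.63 (95% counting interval -0.94 to -0.33), 1.55-fold lower, which did not pass the 2-fold rule. After length correction it was 0.39, in the other direction, and from the most abundant transcript alone -1.25, a difference of more than 2-fold. In wild type its 188 reads went to transcript AT1G08620.2, against 65.9% of reads in the jmj16-labelled library, where AT1G08620.1 took 43.0 reads and AT1G08620.4 took 14.3. These transcripts are of nearly equal length, from 4422 to 4531 nt, and the split of so few reads among them is an estimate. Among the 200 measured genes nearest to it in length and expression, whose median log2 ratio was -1.05 (5th to 95th percentile -1.90 to -0.23), JMJ16 was at the 79th percentile. The count of JMJ16 therefore does not check the label, and an insertion can leave reads from the rest of a gene, so the library is called jmj16-labelled throughout.

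Of 17151 measured genes, 1239 were at least 2-fold higher and 1825 at least 2-fold lower in the jmj16-labelled library. Counting noise alone gave a median of 30.5 higher and 29.5 lower genes over 20 simulated pairs, and 42 at most. These pairs held no length trend and no variation between plants or libraries, so they do not give a rate of false calls. Besides members of the lists described further on, the highest log2 ratios belonged to PUM8 (1 and 108 reads, log2 ratio 5.71, 3.77 to 11.6), a Pumilio RNA-binding protein, and to the receptor-like kinase CRK36 (37.3-fold higher, 17.3 to 127). CTL2, a chitinase-like gene of secondary walls, had 2 and 107 reads (31.0-fold higher, 10.4 to 323). The nitrate transporter NRT2.5 was 12.9-fold higher (7.01 to 30.3), the calmodulin-like CML38 12.3-fold (8.02 to 20.9) and the phosphatase SAL2 11.6-fold (9.16 to 15.1). Of the lowest, GASA6, a gibberellin-regulated peptide, was 26.7-fold lower (20.9 to 35.1), the germin-like GER3 26.3-fold (16.6 to 46.9), the expansin EXPA8 23.0-fold (18.4 to 29.5) and the beta-galactosidase BGAL1 15.6-fold (14.8 to 16.4). The auxin-response repressor IAA29 was 15.3-fold lower (7.85 to 38.4), TRM3 14.0-fold (10.2 to 20.1), the receptor-like protein RLP19 11.2-fold (9.28 to 13.8) and PMI15 6.83-fold (4.85 to 10.05). From the most abundant transcript alone the log2 ratio of IAA29 went from -3.93 to -7.34, of TRM3 from -3.81 to -9.48 and of SAL2 from 3.53 to 4.68.

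Across genes, the log2 ratio was lower for longer transcripts (Spearman rho -0.44). The median was 0.38 in the decile of genes with the shortest transcripts, up to 857 nt, and -0.87 in the decile with the longest, from 2992 nt. In that longest decile 15 genes were higher and 705 lower. Higher genes had a median length of 1288 nt, lower genes 2620 nt and all measured genes 1638 nt. After correction for this trend 1109 genes were higher and 1092 lower, of which 908 and 934 were called in the same direction without it. With log2(TPM + 1) in place of scaled counts, 941 were higher and 747 lower. Of passing genes 55.7% were then higher, against 40.4% with scaled counts. TPM uses the same length for a transcript in both libraries, so it does not correct this trend. Its added 1 shrinks the ratios of genes with low TPM.

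**Figure D1:**
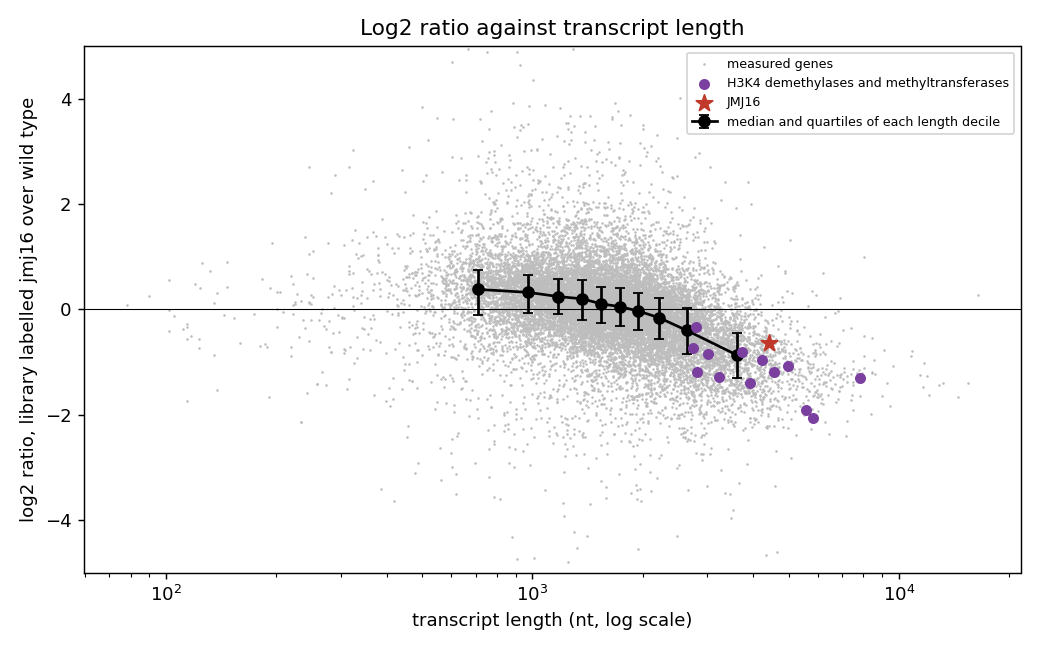
Log2 ratio of the library labelled jmj16 over wild type (vertical axis) against transcript length in nt (horizontal log axis) for 17151 measured genes (grey points; 32 lie beyond the plotted limits of -5 and 5), with the median and quartiles of each decile of genes by length in black, the measured H3K4 demethylases and methyltransferases in purple and JMJ16 as a red star. The medians go from 0.38 at the shortest to -0.87 at the longest transcripts, and all 13 H3K4 enzymes lie below 0.

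Both lists of leaf senescence genes had medians above 0. Of 25 measured senescence transcription factors, 6 were higher, 0 lower and 19 neither, with a median log2 ratio of 0.76 (0.45 to 0.93), above all 10000 random lists. In this list 21 members had a log2 ratio above 0 and 4 below. Whether each member promotes or restrains senescence was not checked, so the median does not give the direction of senescence. WRKY53 (AT4G23810), a regulator that promotes leaf senescence, had 28.8 and 197 reads and was 4.83-fold higher (3.31 to 7.51). NAC087 was 3.01-fold (1.44 to 7.87), NAC019 2.67-fold (2.19 to 3.30) and WRKY25 2.31-fold (2.03 to 2.64) higher. After length correction also WRKY6 (log2 ratio 1.18) passed, so that 7 were higher. From its most abundant transcript alone NAC087 went from a log2 ratio of 1.59 to 5.66. Of 14 measured senescence-associated genes, 7 were higher, 3 lower and 4 neither, with a median of 0.95, above all random lists, while the interval of the median was wide (-1.90 to 3.37). The median was 0.49 over members with at least 100 reads and 0.60 without a minimum. SAG14 (BCB, AT5G20230), a blue copper protein, was 14.2-fold higher (11.3 to 18.4) and SAG13 12.8-fold (8.05 to 22.8), with a log2 ratio of 3.67 that became 8.64 from its most abundant transcript. SAG201 (SAUR36, AT2G45210), an auxin-inducible gene, was 5.05-fold higher (3.59 to 7.46). The nuclease gene BFN1 had 1 and 21 reads, a 10.3-fold ratio with an interval of 2.44 to 626. The 3 lower members belong to genes induced by darkness and low sugar: DIN6 (ASN1), an asparagine synthetase, was 9.22-fold lower (6.49 to 13.8), and also DIN10 5.66-fold (5.26 to 6.09) and SEN1 3.73-fold (3.50 to 3.99). WRKY53 and SAG201 were singled out by the published study on these samples, so their direction is not independent evidence. The protease marker SAG12 had 0 reads in wild type and 0 in the jmj16-labelled library, so it was not measured.

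Photosynthesis genes were lower as a group. Of 45 measured photosynthesis genes, 1 was higher, 3 lower and 41 neither, yet 42 had a log2 ratio below 0 and the median was -0.49 (-0.60 to -0.44), below all 10000 random lists. After length correction 8 were lower and 1 higher. PRK, phosphoribulokinase of the Calvin cycle, was 2.07-fold lower (2.03 to 2.12). RBCS2B, a small subunit of Rubisco, was 2.17-fold lower (2.13 to 2.22), and the light-harvesting gene LHCB1.4 was 6.81-fold lower (6.54 to 7.10). Both have close paralogs that share reads, so their values are uncertain. LHCB4.3 was 2.43-fold higher (2.08 to 2.85). Of 11 chlorophyll synthesis genes 1 was lower and 10 neither, with a median of -0.49 (-0.66 to 0.02) at percentile 0.90. That gene was CHLH, a subunit of magnesium chelatase, 3.56-fold lower (3.37 to 3.77), which no longer passed after length correction (log2 ratio -0.77). CRD1 and PORB had log2 ratios of -0.55 (-0.58 to -0.52) and -0.56 (-0.61 to -0.50). Of 10 chlorophyll breakdown genes 1 was higher and 9 neither, with a median of -0.03 (-0.22 to 0.40) at percentile 20.8. The higher gene was NYE2, a magnesium dechelatase of chlorophyll degradation, at 2.87-fold (2.41 to 3.46), while NYC1 and CLH1 had log2 ratios of -0.46 (-0.56 to -0.37) and -0.03 (-0.12 to 0.06).

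Defence genes of the salicylic acid pathway were higher. Of 16 measured members 7 were higher, 0 lower and 9 neither, with a median log2 ratio of 0.80 (0.08 to 1.96), above all 10000 random lists. PR2 (BGL2, AT3G57260), a beta-glucanase, had 88 and 1431 reads and was 11.7-fold higher (9.45 to 14.7). PR1 was 3.88-fold higher (2.04 to 8.88), the transcription factor CBP60G 4.1-fold (3.64 to 4.64) and the salicylic acid hydroxylase DLO1 6.65-fold (2.68 to 28.4). After length correction also SARD1 (log2 ratio 1.08) passed, so that 8 were higher. The rapid touch, wound and cold response list was higher in the same library, with 6 of 15 members higher, 0 lower, 9 neither and a median of 0.79 (0.23 to 1.25) at percentile 99.985. In it CBF1 was 6.80-fold (4.17 to 12.5), ZAT12 5.94-fold (3.92 to 9.78), RRTF1 2.69-fold (1.05 to 9.84) and TCH2 2.38-fold (1.97 to 2.92) higher. After length correction 4 members were higher: TCH2 (log2 ratio 0.96), RRTF1 (1.28) and also ZAT10 (0.84) no longer passed, while also CZF1 (1.03) did.

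Other hormone lists were mixed. Of 25 jasmonate genes 5 were higher, 2 lower and 18 neither, with a median of 0.43 (0.10 to 0.68) at percentile 99.2, and 0.25 over members with at least 100 reads. The higher ones were the repressor genes JAZ10 (4.11-fold, 2.03 to 10.6), JAZ7 (3.34-fold, 1.36 to 12.1), JAZ5 (3.27-fold, 2.14 to 5.34) and JAZ8 (3.13-fold, 1.14 to 13.8), and also AOC3 (2.45-fold, 1.3 to 5.27). The lower ones were also the lipoxygenase LOX2 (2.35-fold, 2.25 to 2.46) and the defensin PDF1.2 (2.51-fold, 2.26 to 2.79). After length correction LOX2 (log2 ratio -0.63) and JAZ8 (1.31) no longer passed, while also MYC2 (1.39) did, so that 5 were higher and 1 lower. Of 11 ethylene genes 1 was higher and 10 neither, with a median of -0.22 (-0.63 to 0.31) at percentile 68.8. ACS6, which makes the ethylene precursor, was 3.54-fold higher (2.47 to 5.35), and EIN3 had a log2 ratio of -0.44 (-0.53 to -0.36). Of 19 abscisic acid and drought genes 3 were higher, 2 lower and 14 neither, with a median of 0.10 (-0.30 to 0.84) at percentile 68.2. That median was 0.43 with length correction, 0.24 from the most abundant transcripts and 0.19 with total counts. KIN1 was 5.28-fold (3.50 to 8.62), LTI30 3.58-fold (2.93 to 4.44) and COR15A 2.18-fold (1.98 to 2.40) higher. P5CS1, of proline synthesis, was 5.02-fold lower (4.52 to 5.58), and also AAO3 2.13-fold (1.64 to 2.79). After length correction 2 were higher and 1 lower, without COR15A (log2 ratio 0.83) and AAO3 (-0.09). Of 7 cytokinin response genes 1 was higher, 1 lower and 5 neither, with a median of -0.54 (-1.54 to 1.02) at percentile 0.68, and -0.17 after length correction. CRF6 was 2.03-fold higher (1.75 to 2.36) and the response regulator ARR6 2.90-fold lower (2.22 to 3.86), and CRF6 no longer passed after length correction (log2 ratio 0.92).

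Anthocyanin synthesis genes were higher. Of 10 measured anthocyanin and flavonoid genes 7 were higher, 0 lower and 3 neither, with a median log2 ratio of 2.62 (0.35 to 6.10), above all 10000 random lists. DFR, which makes leucoanthocyanidins, had 0 and 53 reads, at least 12.7-fold higher against the floor of 3 counts in the wild type library. TT19 (GSTF12), needed for anthocyanin transport to the vacuole, had 1 and 142 reads, a 68.5-fold ratio with an interval of 18.1 to 4073. The MYB activator PAP2 had 2.0 and 70.9 reads (20.6-fold, 6.83 to 216) and the glycosyltransferase UF3GT 2.0 and 43.0 (12.5-fold, 4.04 to 132). The size of the median rests on members with few wild type reads: it was 1.44 over members with at least 100 reads and 1.32 with log2(TPM + 1). No passing member was found among 20 nutrient recycling and proteolysis genes, whose median was 0.32 (0.06 to 0.43) at percentile 89.8. The proteases RD19A and GAMMA-VPE, the most read of them, had log2 ratios of 0.50 (0.47 to 0.52) and 0.43 (0.41 to 0.45). Of 12 flowering and ageing genes 1 was higher, 1 lower and 10 neither, with a median of 0.18 (-0.64 to 0.74) at percentile 30.6. TSF, a floral inducer, was 3.21-fold higher (1.29 to 11.6), and FLC, a floral repressor, had 22 and 6 reads and was 4.80-fold lower (2.0 to 15.3). Of 15 circadian clock genes 0 were higher, 2 lower and 13 neither, with a median of -0.60 (-0.78 to 0.24) at percentile 0.50, and -0.21 after length correction. PRR7 was 4.1-fold lower (3.74 to 4.51) and RVE1 2.71-fold (1.77 to 4.29).

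Of 13 other measured genes listed as H3K4 demethylases or methyltransferases 8 were lower and 5 neither. Whether H3K4 is the main target of each was not checked. Their transcripts were long, with median lengths of 2918 nt for demethylases and 4565 nt for methyltransferases. Of 6 measured H3K4 demethylases 0 were higher, 3 lower and 3 neither, with a median log2 ratio of -1.01 (-1.92 to -0.33). LDL3 was 3.79-fold lower (2.78 to 5.28), JMJ14 2.45-fold (1.99 to 3.03) and LDL2 2.27-fold (1.27 to 4.21). Of 7 H3K4 methyltransferases 0 were higher, 5 lower and 2 neither, with a median of -1.19 (-2.06 to -0.80). SDG8 was 4.16-fold lower (2.87 to 6.26), ATX2 2.63-fold (1.96 to 3.57), SDG2 2.46-fold (1.83 to 3.34) and ATX5 2.29-fold (1.65 to 3.21), and also ATXR7 2.11-fold (1.49 to 3.03). The medians were at percentiles 0.66 and 0.25 of lists matched on expression alone, but at percentiles 14.0 and 21.1 of lists matched on length too. After length correction the medians were -0.43 and 0.02 and 0 members passed. From the most abundant transcript alone the log2 ratio of JMJ14 went from -1.29 to -0.17, that of LDL3 from -1.92 to -1.45 and that of ATX2 from -1.39 to -3.79.

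Some markers of other tissues differed. Of 7 vascular markers 3 were higher, 0 lower and 4 neither, with a median of 0.98 (-0.66 to 2.42) at percentile 99.9. All 3 are genes of xylem: XCP2 was 3.07-fold (1.93 to 5.29) and XCP1 3.47-fold (1.42 to 12.5) higher, and CESA8 had 2 and 18 reads (5.34-fold, 1.55 to 57.7). The median depended on these low counts: it was -0.54 over members with at least 100 reads and 0.17 with the most abundant transcript of each gene. Length correction gave 4 higher members, with also CESA4 (log2 ratio 1.56). Of 4 floral and seed markers 0 were higher, 2 lower and 2 neither, with a median of -2.63, or -2.18 with CRA1 at its bound, at percentile 0.02. SEP1 had 34.5 and 2.06 estimated counts (19.7-fold lower, 6.23 to 208), and the seed storage gene CRA1 had 23 and 0, at least 10.6-fold lower against the floor of 3 counts in the jmj16-labelled library. Without a minimum of reads the median was -0.96. Of 5 epidermis and guard cell markers 0 were higher, 2 lower and 3 neither, with a median of -0.61 at percentile 20.7. KAT1 was 2.11-fold lower (1.58 to 2.84) and FAMA 2.0-fold (1.56 to 2.58), and neither passed after length correction. Of 4 heat shock genes 1 was higher, 2 lower and 1 neither, with a median of -0.57 at percentile 26.9. HSP101 was 2.94-fold (1.46 to 6.54) and HSP90.1 2.52-fold (1.98 to 3.25) lower, and HSP18.2 was 2.36-fold higher (1.03 to 6.80). After length correction HSP101 (log2 ratio -0.84) and HSP18.2 (0.96) no longer passed, and without a minimum of reads the median was 0.20. The cell division list had 1 measured member, CDKB2;1, with a log2 ratio of -0.08 (-1.43 to 1.37) at percentile 41.1. Neither of the measured shoot apex and root markers passed: SCR had a log2 ratio of -0.21 (-0.50 to 0.07) and SHR of 0.92 (0.47 to 1.4), with a median of 0.35 at percentile 92.4. SHR passed as higher after length correction (1.1). Of 7 reference genes 0 passed, with a median of 0.00 (-0.55 to 0.99) at percentile 31.2. UBQ10 had a log2 ratio of 0.00 (-0.02 to 0.03) and ACT2 of -0.34 (-0.39 to -0.28).

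**Figure D2:**
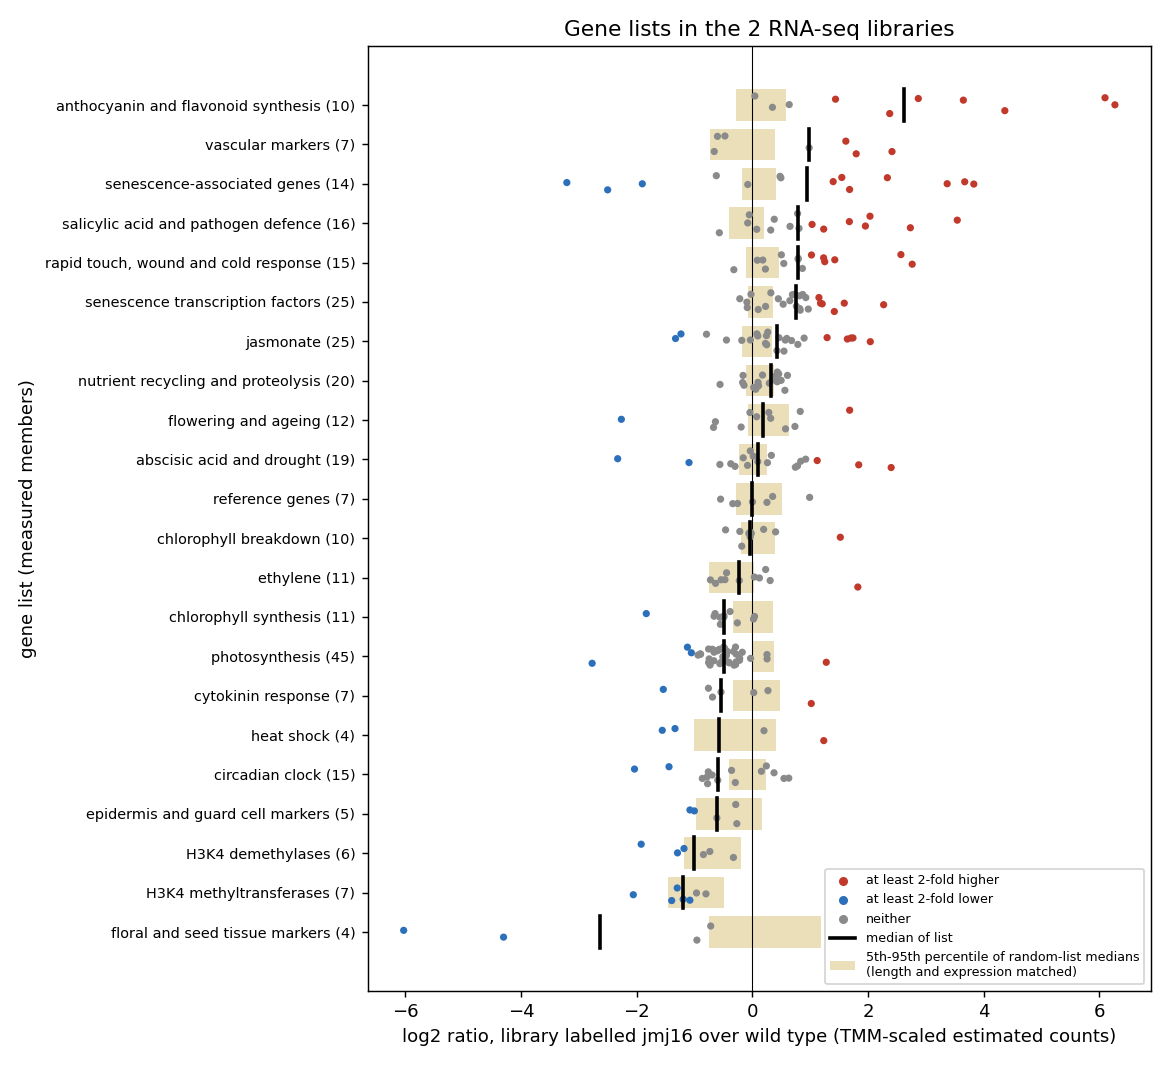
Log2 ratio of the library labelled jmj16 over wild type (horizontal axis) for each measured member of the 22 gene lists with at least 4 measured members (vertical axis, number measured in brackets); points are genes, red at least 2-fold higher, blue at least 2-fold lower and grey neither, black bars are list medians, and pale bands span the 5th to 95th percentile of medians of 10000 random lists matched on length and expression. The anthocyanin median of 2.62 lies right of its band and the photosynthesis median of -0.49 left of its band, while both H3K4 enzyme medians lie inside theirs.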

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

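The length correction was chosen after the trend had been seen, and the other alternatives were fixed beforehand. The plan matched random lists on expression alone, so the percentile matched on length too was an addition to it. On expression alone the percentile was 11.7 instead of 68.8 for ethylene, 75.7 instead of 30.6 for flowering and 4.19 instead of 0.68 for cytokinin. The count of higher genes (1239) became 747 with at least 100 reads, 2821 at 1.5-fold, 255 at 4-fold and 487 with the counting interval beyond 2-fold. That of lower genes (1825) became 1199, 3355, 292 and 807 in the same order, 747 with TPM and 1092 with length correction. A stricter or looser rule moves these counts by its construction; for TPM the cause was not tested. With length correction the H3K4 methyltransferase median turned from -1.19 to 0.020, JMJ16 from -0.63 to 0.39 and SDG2 from -1.30 to 0.16, since their transcripts are long, and the ethylene median went from -0.22 to 0.40. The photosynthesis median (-0.49) was -0.72 with length correction, -0.40 with total counts and -0.43 with TPM. TPM gave -0.58 for the methyltransferases. JMJ16 was at -1.25 from its most abundant transcript alone, where 43.0 and 14.3 reads of other transcripts are left out. Without a minimum of reads the shoot apex and root median went from 0.35 to -0.47, on members with 1 read. Of 214 list medians recomputed, 207 stayed within their interval, as did 490 of 600 values of 86 named genes. In short lists that interval is near the range, so large moves stay inside it. The vascular median went from 0.98 to -0.54 with at least 100 reads, 0.17 with the most abundant transcript and 0.36 with TPM. The heat shock median went from -0.57 to 0.20 without a minimum of reads. The floral median went from -2.63 to -0.96 without a minimum, -0.98 with the most abundant transcript and -0.88 with TPM. The senescence-associated median went from 0.95 to 0.49 with at least 100 reads and 0.60 without a minimum, and the jasmonate median from 0.43 to 0.25 with at least 100 reads. Length correction took the demethylase median from -1.01 to -0.43, the clock median from -0.60 to -0.21, the cytokinin median from -0.54 to -0.17, the heat shock median to -0.14, the nutrient recycling median from 0.32 to 0.21 and the shoot apex and root median to 0.69. TPM took the demethylase median to -0.57 and the heat shock median to -0.11. The flowering median (0.18) was 0.27 with total counts and 0.34 with the most abundant transcript, and the ethylene median -0.13 with total counts and -0.09 with TPM. The anthocyanin median went from 2.62 to 1.44 with at least 100 reads and 1.32 with TPM. Medians near 0 changed sign for chlorophyll breakdown, cell division, reference genes, flowering (-0.03 with length correction) and ethylene (0.04 with at least 100 reads). Of these the reference genes reached 0.33 with the most abundant transcript and cell division -0.29 without a minimum. The abscisic acid median (0.10) was 0.43 with length correction, 0.24 with the most abundant transcript, 0.19 with total counts and 0.17 with TPM. The most abundant transcript alone took JMJ14 from -1.29 to -0.17 and LDL3 to -1.45, and moved others away from 0: ATX2 to -3.79, NAC087 to 5.66, SAG13 to 8.64, SAL2 to 4.68, IAA29 to -7.34 and TRM3 to -9.48. Genes with few reads shrank with TPM, such as CRA1 from -6.03 to -1.18, DFR from 6.27 to 1.82 and SEP1 from -4.30 to -1.61. The log2(TPM + 1) value was below 2-fold for the named H3K4 enzymes, NAC087, PRK, JAZ8, RVE1, RRTF1, HSP101, HSP18.2, XCP1, CESA8, FAMA and KAT1, and that with an added count of 5 for JAZ8, RRTF1, HSP18.2 and FAMA. Total counts put PRK, FAMA and KAT1 below 2-fold. The scalings moved the median of all genes by at most 0.09. The cell division and floral lists kept no member with 100 reads. No paired analysis was possible with 1 library per genotype. Depth limits genes with few reads: JAZ8, with 4 and 19, has an interval of 1.14 to 13.8.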

Other observations

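The gene families, the test of reads from outside the insertion, the test of a wrong label and the low-energy list were chosen after results had been seen. Grouped by symbol, 101 families with at least 10 measured genes were set among random lists matched on length and expression. Of these, 12 lay above and 9 below the central 95% of their random lists. If members varied independently, 2.53 would be expected in either direction. Members of a family can vary together and near-identical paralogs share reads, so the 12 and 9 do not measure an excess over chance. The WRKY family (41 genes, 9 higher, 2 lower) had a median log2 ratio of 0.67 (0.30 to 0.87) at the 100th percentile, and the NAC family (35 genes, 7 higher, 1 lower) 0.45 (0.19 to 0.82) at percentile 99.9; both hold members of the senescence transcription factor list. Outside that list also WRKY61 had a log2 ratio of 2.42 and also NAC090 one of 2.63. The symbols TIM and TOM include genes of protein import into mitochondria, but what each member does was not checked. These families had medians of 0.74 (0.37 to 1.14) and 0.65 (0.41 to 0.82), with 3 of 11 and 0 of 12 members passing, at percentiles 99.6 and 99.4. RLP, to which the lower RLP19 belongs, had 9 of 40 members higher and 4 lower, with a median of 0.12 (-0.19 to 0.24) at the 100th percentile. The other families above the central 95% were CNGC, TCP, ERD, ECT, ARF, SCPL and GLR. That place is relative to lists of like length and expression, and the ratios themselves need not be high. The GLR median was -0.19 (-1.10 to -0.003), with 1 member higher and 2 lower. ARF had a median of 0.06, with 1 higher and 2 lower, and CNGC one of 0.26, with 0 higher and 1 lower.

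The 9 low families were PDF, AGP, BGAL, RALFL, SEC, CRR, IAA, HCF and IQD. PDF, a symbol shared by defensins and other genes, had 6 of 10 members lower and 1 higher, with a median of -1.23 (-1.83 to 0.75) at percentile 0.01. The beta-galactosidase family BGAL had 8 of 12 members lower and 0 higher, with a median of -1.37 (-2.49 to -0.86) at percentile 0.09, and -1.03 after length correction. The auxin-response family IAA had 5 of 15 members lower and 0 higher, with a median of -0.29 (-1.66 to 0.51) at percentile 0.28. Its lower members were IAA29 and also IAA19 (log2 ratio -2.43), IAA7 (-1.75), IAA1 (-1.66) and IAA2 (-1.14). The expansin family EXPA, to which the lower EXPA8 belongs, had 2 of 10 members higher and 3 lower, with a median of 0.08 at percentile 32.7. The medians of PDF, BGAL and IAA kept their sign under every scaling, TPM and the length correction.

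The lower log2 ratios of the H3K4 enzymes may come from length-dependent read yield rather than from the genotype. All 13 measured enzymes of both lists had a log2 ratio below 0 (median -1.18), but that median lay at percentile 7.50 of random lists matched on length and expression, inside the 5th to 95th percentile. Loss of the far end of long RNA was examined within 1799 genes by the difference between their longest and shortest transcripts, with a median of -0.056 (-0.12 to 0.01), which leaves it open. Library preparation and genotype cannot be told apart with 1 library each.

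The lower count of JMJ16 in the jmj16-labelled library may come from length-dependent read yield, since its ratio was at the 79th percentile of 200 genes of like length and expression. That would lower the count and says nothing on why reads remain. The 168 reads could come from outside the insertion, which cannot be told apart from an intact transcript because the tables hold no positions. A wrong sample label cannot be told apart either, since the length-corrected log2 ratio of 0.39 is what an intact gene and what reads from the rest of a disrupted gene can both give. WRKY53 and SAG201 were 4.83-fold and 5.05-fold higher in the library labelled jmj16, the direction that fits the label if JMJ16 lowers their transcripts, but these genes were singled out by the study on the same samples and do not settle it.

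The higher senescence-associated, defence and anthocyanin genes are not accounted for by length-dependent read yield, since each list lay at the 100th percentile of lists matched on length and expression. Handling of the leaves before freezing may have contributed to part of them, which was not tested on those genes. The touch, wound and cold list, of other genes, lay at percentile 99.985, with CBF1 and ZAT12 among its higher members. That value cannot decide what raised the senescence-associated, defence and anthocyanin genes. Whether that list responds to handling alone was not tested. Loss of JMJ16 and a difference in the age, growth or time of harvest of the plants, untested in this design, stay open beside handling.

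The lower sugar-repressed senescence markers DIN6, DIN10 and SEN1 led to the hypothesis of better sugar supply in the leaves labelled jmj16. A separate list of 14 low-energy genes, without those 3, had 13 measured members after SEN5 was left out because the reference did not carry its name. They had 3 lower, 1 higher and 9 neither, with a median of -0.69 (-1.11 to -0.19) at percentile 0.07 of lists matched on length and expression. MCCA and MCCB, of leucine breakdown, were 2.99-fold (2.51 to 3.58) and 2.29-fold (1.95 to 2.69) lower and the trehalose-phosphate synthase TPS9 2.17-fold (1.80 to 2.61), while BCAT2 was 2.26-fold higher (2.02 to 2.53). After length correction 4 were lower: TPS9 (log2 ratio -0.53) no longer passed, while also DRM1 (-1.06) and DRM2 (-1.15) did. The value fits better sugar supply in those leaves. It also fits loss of JMJ16, or any other difference in light or time of harvest that lowers these genes. None of these alternatives was tested. The circadian clock list was low too, with a median of -0.60 at percentile 0.50 and of -0.21 after length correction. Of its 15 members 10 had a log2 ratio below 0 and 5 above. What this says of the time of harvest was not tested.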
